A study of Mus musculus with 7 samples.

How the data were processed

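Total RNA of MS-1 cells was profiled in 7 libraries, 3 labelled control (wild type) and 4 labelled LPL overexpression. MS-1 is a mouse endothelial cell line derived from pancreatic islets. Per the labels' protocols, cells were grown in DMEM, RNA was extracted with a Qiagen RNeasy kit and libraries were made with the TruSeq stranded total-RNA kit. Groups and replicate numbers came from the sample titles. Neither the species of the LPL coding sequence nor the way it was introduced is given in the labels, and the control is named as wild type, with no vector-only library among those analysed. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which can be technical.

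Reads were aligned by the authors with STAR to the mouse build mm10, per the submitters' processing notes. The versions and the annotation release are not given in the sources used here. Each of the 7 deposited files lists the same 49585 genes with Ensembl identifiers, symbols, coordinates and exonic length. The deposited read counts per gene are whole numbers and not normalized, and per the file headers they are given for both read orientations together and for each orientation. The deposited FPKM values were scaled per 1000000 reads counted on the autosomes without ribosomal RNA genes, a denominator that the values themselves return, or over all genes in a second set of columns. One set of the authors' TPM columns sums to 1000000 over all genes. The other set, which the authors scaled to autosomal genes and which therefore sums to more than that, was treated as a score and not used in a test. FPKM values were not used in a test either. Coordinates are those of the files, 1-based, on mm10. Gene types came from the GENCODE vM21 annotation of the same build, in which 49326 of the 49585 identifiers were found without their version suffix and 45128 had the same start and end.

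Reads in reverse orientation, the sense orientation of this kit, made up between 97.0% and 97.1% of oriented reads per library and were the counts used. They summed to between 24328418 and 29210847 per library, and between 13037 and 13687 genes had at least 10 counts. Counting error alone is covered by the intervals and floors given, because reads without molecular identifiers are not independent molecules. A group with no read of a gene was assigned a floor of 3 counts over the group, 0.0372 CPM in the controls, and fold changes against such a group are given as lower bounds. With 1 to 3 reads, and for Lpl and Fabp5, the ratio of pooled CPM is given with an exact (Clopper-Pearson) 95% counting interval.

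Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM normalization, filterByExpr by group, a model with the group as its only term and robust dispersion. P-values were adjusted by Benjamini-Hochberg over all 13639 genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F, and can be too small where a group holds few reads. Levels are TMM-scaled CPM, given as mean ± SD. The level of Lpl was also compared by an exact two-sided permutation test over all 35 splits of the 7 libraries. Before the data were examined, 32 gene lists were fixed. Those with at least 5 members tested (28) were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, Lpl left out, and adjusted over lists. Camera with an estimated correlation and fry were run beside it. Symbols of 5 list members were replaced by the older symbols in the files. Counts adjusted over the list alone use the members of that list only. After the data had been seen, 4 lists were added, for melanosome genes, transcription factors and receptors of the pigment lineage, Schwann cells and retinal pigment epithelium. They were adjusted among themselves.

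Genes named in the text were chosen by a rule fixed before the data were examined. It takes Lpl, 12 genes of lipid handling and endothelial identity whatever their result, and the 12 largest rises and 12 largest falls past the threshold with a mean of at least 2 CPM, groups that do not overlap and no predicted or clone name. It also takes up to 3 members of each list with the lowest adjusted p and up to 3 more, by size of change, from lists that were called. Members of the added lists and other genes said to be chosen after their values were seen fall outside it. Genes with near-identical copies, such as the stefin A, histone and interferon-induced families, are uncertain where the counting could divide reads among copies, and 186 gene rows share their symbol with another row.

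The edgeR and camera steps were tested on simulated counts for the comparison of LPL overexpression with control, drawn for the 13639 genes with 200 of them changed. Of the 50 genes changed at each size, 30% (15 genes) were recovered at 1.1-fold, 80% (40) at 1.25-fold, 98% (49) at 1.5-fold and 100% (50) at 2-fold. Beside these calls stood 14 false calls, among 13439 unchanged genes. The data held 5888 called genes and changes above 2-fold, so these rates may not hold there. Camera called 0 of 200 random lists. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists whose genes vary together. Alternatives were RLE and upper-quartile factors, other filters, DESeq2 1.42.0, limma voom, limma trend on log2(TPM + 0.5) and log2(TPM + 1), the replicate number as a block, each library left out in turn, removal of abundant non-coding and mitochondrial RNA, protein-coding genes only, a stricter threshold, and glmTreat against a fold of 1.5. Counts of both orientations and a test without genes of at most 3 control counts were added after the data had been seen. Tables were read with pandas 2.3.3 and plots were drawn with matplotlib 3.10.9 under Python 3.11.15.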

Results

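Gene expression was measured by RNA sequencing in MS-1 cells, a mouse endothelial line, in 3 control libraries and 4 libraries labelled as overexpressing lipoprotein lipase (LPL), the enzyme that releases fatty acids from circulating triglyceride. Counted reads numbered 27386023, 28104402 and 26514501 in control replicates 1 to 3. The LPL overexpression replicates 1 to 4 held 24328418, 29210847, 24911147 and 27542365. The comparison asks how overexpression of the lipase alters the transcriptome of endothelial cells. Libraries of one group were close to each other, with Pearson's r of log2 CPM across genes from 0.996 to 0.997 within groups and from 0.959 to 0.962 between groups, where genes are not independent replicates. The first principal component held 89.4% of the variance and separated the groups.

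Lpl was close to absent in the controls and abundant in each LPL overexpression library. The gene (ENSMUSG00000015568.16) lies on the plus strand of chromosome 8 of mm10, from 68880491 to 68907448, and the reads were counted over its exons. It had 1, 1 and 6 counts in the controls, against 10867, 12691, 10901 and 12753 in the LPL overexpression libraries. The level was 0.101 ± 0.112 CPM (SD, n = 3) in the controls and 441 ± 13.1 CPM (SD, n = 4) with overexpression. In edgeR's quasi-likelihood test the log2 fold change was 12.05 with a standard error of 0.08 (adjusted p = 5.99e-55), higher in 4 of 4 libraries. Counts per gene do not separate an introduced coding sequence from the cell's own Lpl, and the same 4 libraries carried genes of pigment cells. An exact two-sided permutation test over the 35 splits gave p = 0.0286, the smallest this design can give. The log2 fold change was 13.39 without control replicate 3, which held 6 of the 8 control reads, and 7.09 on log2(TPM + 1).

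**Figure D1:**
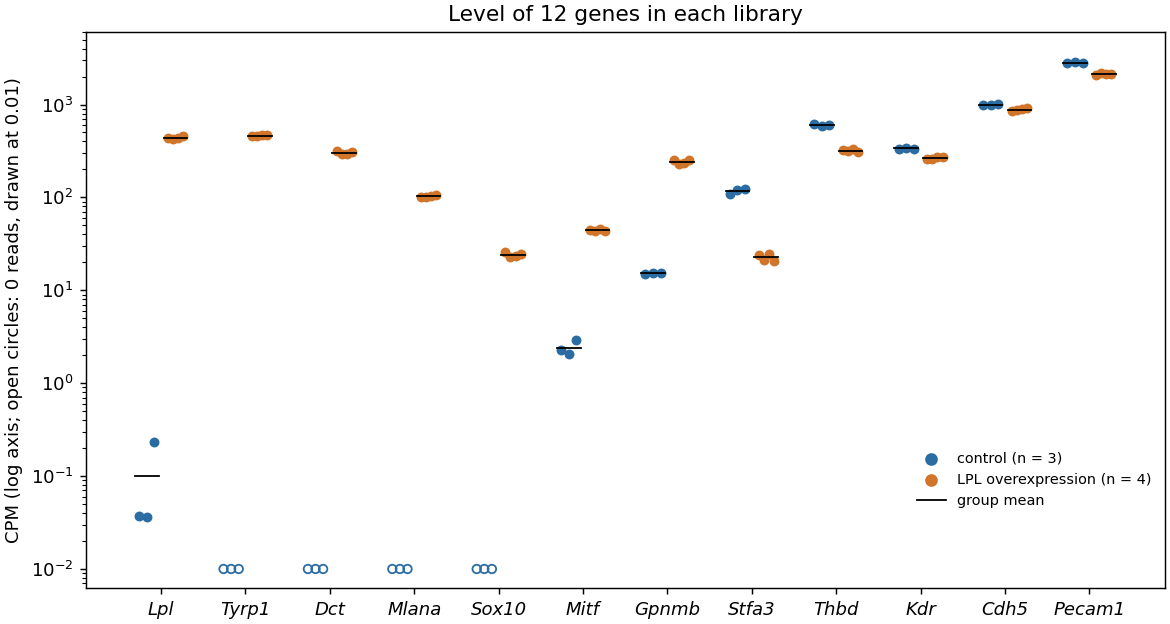
Level of 12 genes in each library in TMM-scaled CPM on a log axis; each point is a library, bars are group means, and open circles mark libraries with 0 reads, drawn at 0.01. Tyrp1, Dct, Mlana and Sox10 had 0 reads in all 3 controls, while Pecam1 had between 2094 and 2181 CPM in the 4 LPL overexpression libraries.

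The largest rises besides Lpl included genes of pigment cells, which had few or no reads in the controls. Tyrp1, a melanosomal enzyme of melanin synthesis on chromosome 4 (80834123 to 80851719, mm10), had 0 reads in the 3 controls and 462 ± 4.84 CPM (SD, n = 4) in the LPL overexpression libraries, at least 12420-fold above the control floor. Dct, the dopachrome tautomerase gene on chromosome 14, rose from 0 reads to 302 ± 11.7 CPM, at least 8112-fold. Mlana, which encodes a melanosome protein, rose from 0 reads to 103 ± 2.55 CPM, at least 2777-fold. Tyr, the gene of tyrosinase, rose from 0 reads to 42.1 ± 1.87 CPM, and Sox10, a transcription factor of the neural crest, from 0 reads to 24.1 ± 1.49 CPM. Others of the 12 largest rises were Mlph, Abca12, Tspan10, Car14, Gpc1, Fkbp6 and Slc45a2. Slc45a2, a melanosomal transporter, had 1 control read and a ratio of 4911 (95% counting interval 881 to 194000).

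Lists of pigment cell genes were written after these genes had been seen and include several of them, so no set test of the melanosome and lineage lists is given. Of 22 tested genes of melanosomes and pigment synthesis, 18 rose and 1 fell, and adjusted over the list alone the counts were 18 and 1. The median log2 fold change was 7.27, or 6.79 with genes of 0 control reads at their bound. Pmel, the gene of the melanosome fibril protein, rose from 0.952 ± 0.141 to 337 ± 11.5 CPM. Of 11 tested transcription factors and receptors of the lineage, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 6.50, or 4.85 at the bound. The other 5 of its 16 members, Ednrb, Foxd3, Lef1, Ngfr and Tfap2b, had 0 to 2 reads over each group and were not tested. Mitf, the master transcription factor of melanocytes, rose from 2.41 ± 0.446 to 44.4 ± 0.896 CPM. Pax3 had 2 control reads and 10.7 ± 1.02 CPM in the LPL overexpression libraries, while Kit stood at 90.0 ± 2.26 and 90.1 ± 5.68 CPM. Of 5 tested Schwann cell genes, 2 rose and 2 fell over all genes and over the list alone (camera adjusted p = 0.690). Of 2 tested genes of retinal pigment epithelium 0 rose and 1 fell, or 0 and 2 adjusted over the list alone. Summed over the 10 melanosome genes with at most 3 control reads, the level was between 1062 and 1111 CPM in the 4 LPL overexpression libraries and between 0.0362 and 0.111 CPM in the controls.

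Over all genes, 5888 of 13639 (43.2%) changed, 2988 higher and 2900 lower with LPL overexpression, and most changes were small. Of the changed genes, 80.4% differed by less than 1.5-fold. At least 2-fold changes were nearly all rises, with 618 genes higher and 70 lower, and at least 4-fold changes numbered 403 and 5. Among the 618 were 235 genes with at most 3 reads over the 3 controls, and no tested gene had as few reads over the LPL overexpression libraries. The groups did not overlap in 44.6% of genes tested, where chance gives 5.71%. Of the changed genes 50.8% were higher, a share that was 61.3% with limma trend on log2(TPM + 0.5) and 59.2% with upper-quartile factors (3513 higher, 2426 lower). Of the genes named here as changed by the rule set beforehand or in the added lists, only Lmf1 and Plin2 had fewer than 4 of 4 LPL overexpression libraries beyond all 3 controls.

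The largest falls were in genes with low to moderate levels. Stfa3 and Stfa2, neighbouring genes on chromosome 16 for stefin A cysteine protease inhibitors with near-identical copies, had log2 fold changes of -2.38 (SE 0.05) and -2.95 (SE 0.10). Stfa3 fell from 117 ± 8.21 to 22.6 ± 1.72 CPM and Stfa2 from 14.4 ± 1.31 to 1.88 ± 0.407 CPM. Chil5 fell from 42.9 ± 1.70 to 15.6 ± 1.27 CPM. Nov, which encodes a matricellular protein, fell from 124 ± 3.67 to 52.0 ± 1.76 CPM, and Slc14a1, a urea transporter gene, from 70.7 ± 1.80 to 29.8 ± 0.725 CPM. The remaining genes of the 12 largest falls were Plet1, Lhx9, Ifi209, Gap43, Plag1, Wnt7b and Serpinb9b.

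**Figure D2:**
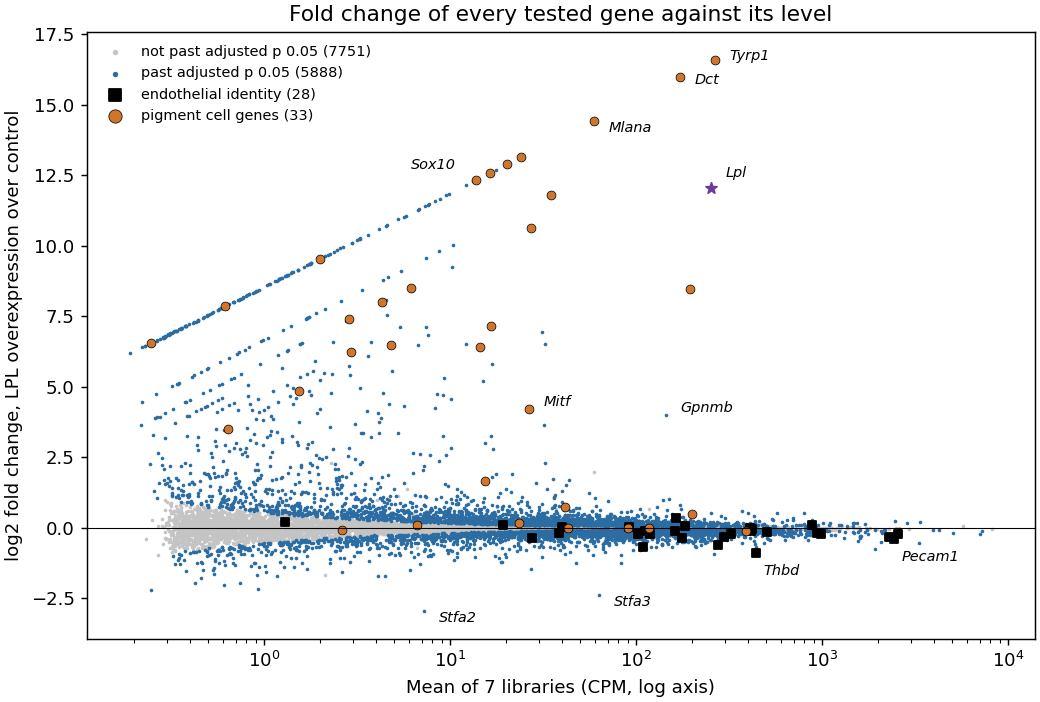
Log2 fold change of each of the 13639 tested genes against its mean CPM over 7 libraries on a log axis; 5888 genes past an adjusted p of 0.05 are blue, the 33 tested pigment cell genes orange and the 28 endothelial identity genes black. The rises reach far beyond the falls, and the fitted values of genes with 0 control reads, which form the upper diagonal line, depend on the prior count.

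Of the 28 lists tested, 8 were called by camera, 7 upward and 1 downward, and 0 were called with an estimated correlation. Another split of the 7 libraries called as many lists, with LPL overexpression replicates 2, 3 and 4 set against the controls and replicate 1. That split keeps most of the contrast between the groups.

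Genes of endothelial identity were the list called downward. Of 28 members tested, 19 fell, 3 rose and 6 did not pass, with the same counts of falls and rises adjusted over the list alone, a median log2 fold change of -0.18 and adjusted p = 3.62e-04 (adjusted p = 0.306 with an estimated correlation). Thbd, the gene of the anticoagulant receptor thrombomodulin, fell from 598 ± 12.9 (SD, n = 3) to 320 ± 7.82 CPM (SD, n = 4), a log2 fold change of -0.90 (SE 0.02). Plvap, which encodes the protein of fenestral diaphragms, had a log2 fold change of -0.62 (SE 0.03) and Ly6c1 of -0.68 (SE 0.05). Pecam1, the adhesion molecule gene on chromosome 11 (106654217 to 106750628, mm10), fell from 2823 ± 14.9 to 2145 ± 36.7 CPM, a log2 fold change of -0.40 (SE 0.02, adjusted p = 9.25e-20 in edgeR). Kdr, the main receptor of VEGF, fell from 336 ± 5.05 to 267 ± 7.41 CPM and Cdh5, the gene of VE-cadherin, from 997 ± 18.9 to 884 ± 25.8 CPM. Each LPL overexpression library lay below each control for these 6 genes. Their fall went with the pigment cell genes. In every one of these libraries the 10 melanosome genes with at most 3 control reads summed to at least 1062 CPM.

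Angiogenesis and activation genes changed in both directions and neither list was called. Of 38 angiogenesis and tip cell genes, 8 rose and 17 fell, 9 and 17 adjusted over the list alone (adjusted p = 0.497). Nrp2, a co-receptor of VEGF family ligands, rose from 22.2 ± 1.70 to 46.7 ± 2.02 CPM, and Sema3f fell from 67.8 ± 1.43 to 50.6 ± 1.71 CPM. Vegfc had 0 control reads and 1.20 ± 0.230 CPM with overexpression, at least 32.4-fold more. Those libraries also carried the pigment cell genes, and which cells gave the Vegfc and Nrp2 reads was not tested. Of 24 endothelial activation and NF-kB targets, 3 rose and 8 fell over all genes and over the list alone (adjusted p = 0.497). Selp, the gene of P-selectin, fell from 232 ± 3.06 to 170 ± 8.67 CPM, Tnfaip2 from 318 ± 5.36 to 230 ± 8.14 CPM and Ptgs2 from 66.5 ± 1.72 to 49.9 ± 0.937 CPM.

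Genes that handle LPL and its products did not move together. Of 13 tested genes for LPL processing, cofactors and related lipases, 5 rose and 2 fell over all genes and over the list alone (adjusted p = 0.641). Angptl4, an inhibitor of LPL, fell from 45.0 ± 2.22 to 32.7 ± 1.75 CPM, a log2 fold change of -0.46 (SE 0.04). Sort1 rose from 10.3 ± 0.256 to 24.6 ± 1.61 CPM and Apoe, an apolipoprotein gene, had a log2 fold change of 3.67 (SE 0.06). The libraries with these rises also carried the pigment cell genes, and which cells gave the added reads was not tested. Gpihbp1, which anchors LPL on capillary endothelium, was at 2.02 ± 0.130 and 2.21 ± 0.236 CPM, a log2 fold change of 0.12 (SE 0.15) that did not pass (adjusted p = 0.560 in edgeR). Lmf1, needed for LPL maturation, had a log2 fold change of 0.15 (SE 0.05, adjusted p = 0.0199 in edgeR). The call of Lmf1 ended with DESeq2 (adjusted p = 0.0679), on TPM values, and without control replicate 2 (adjusted p = 0.155), LPL overexpression replicate 1 (0.108) or LPL overexpression replicate 3 (0.0554).

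Fatty acid uptake, oxidation and storage genes changed in both directions, and none of their 5 lists was called. Of 14 uptake and transport genes, 3 rose and 5 fell, 4 and 5 adjusted over the list alone (adjusted p = 0.988). Fabp5, a fatty acid binding protein gene, rose from 0.508 ± 0.0899 to 28.8 ± 0.928 CPM, a log2 fold change of 5.81 (SE 0.11), while Fabp4 was at 1.48 ± 0.257 and 1.62 ± 0.139 CPM. The libraries in which Fabp5 rose also carried the pigment cell genes, and which cells gave its reads was not tested. Cd36 had 1 read in each group and was not tested. Of 24 PPAR targets, 9 rose and 4 fell, 9 and 5 adjusted over the list alone (adjusted p = 0.406). Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose from 87.7 ± 1.41 to 107 ± 3.62 CPM, and Pdk4 was at 3.35 ± 0.160 and 3.27 ± 0.268 CPM. Of 25 beta-oxidation genes, 8 rose and 2 fell (adjusted p = 0.223), and of 21 lipid droplet, triglyceride synthesis and lipolysis genes 9 rose and 4 fell (adjusted p = 0.493), with the same counts over each list alone. Plin2, a lipid droplet coat gene, had a log2 fold change of 0.14 (SE 0.05, adjusted p = 0.0129 in edgeR). The call of Plin2 ended with DESeq2 (adjusted p = 0.0555) and without control replicate 1 (0.0596), LPL overexpression replicate 2 (0.0620) or LPL overexpression replicate 3 (0.0506). Of 14 LXR targets and cholesterol efflux genes, 6 rose and 2 fell over all genes and over the list alone (adjusted p = 0.116). The LXR list passed with no filter on low counts (adjusted p = 0.0448), and in the other settings of camera its adjusted p was between 0.0599 and 0.576.

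Both lists of lipid synthesis genes were called upward, with more members higher than lower. Of 25 cholesterol biosynthesis genes, 12 rose and 2 fell, with a median log2 fold change of 0.16 and adjusted p = 0.00284 (adjusted p = 0.306 with an estimated correlation). Insig1, a sterol-regulated gene, rose from 30.9 ± 3.40 to 47.9 ± 1.21 CPM. Of 20 fatty acid synthesis and desaturation genes, 13 rose and 1 fell, with a median of 0.12 and adjusted p = 0.00284 (adjusted p = 0.306 with an estimated correlation). Scd2, a stearoyl-CoA desaturase gene, rose from 633 ± 14.9 to 915 ± 39.7 CPM, Slc25a1, the mitochondrial citrate carrier gene, from 21.3 ± 1.35 to 38.3 ± 0.887 CPM, and Fads2 from 45.6 ± 0.494 to 63.4 ± 2.50 CPM. The same counts held over each list alone. In all 4 libraries with these rises, the 10 melanosome genes with at most 3 control reads summed to 1062 CPM or more.

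The lists of the unfolded protein response, lysosomes and respiration were also called upward. Of 26 unfolded protein response genes, 16 rose and 0 fell, 17 and 0 adjusted over the list alone, with a median of 0.13 and adjusted p = 3.62e-04 (adjusted p = 0.163 with an estimated correlation). Calr, an endoplasmic reticulum chaperone gene, rose from 598 ± 12.7 to 761 ± 5.84 CPM, and Xbp1, a transcription factor of the response, from 69.4 ± 2.46 to 90.6 ± 1.74 CPM. Of 30 lysosome and autophagy genes, 13 rose and 3 fell over all genes and over the list alone, with a median of 0.06 and adjusted p = 0.00284 (adjusted p = 0.306 with an estimated correlation). Its 2 largest rises were Mitf and Gpnmb, a melanosome glycoprotein gene that went from 15.2 ± 0.377 to 242 ± 11.8 CPM. Atp6v0d1, a subunit of the lysosomal proton pump, rose from 44.3 ± 1.44 to 67.5 ± 1.46 CPM. Of 38 nuclear-encoded oxidative phosphorylation genes, 21 rose and 1 fell over all genes and over the list alone, with a median of 0.07 and adjusted p = 0.00523 (adjusted p = 0.576 with an estimated correlation). Sdhb rose from 82.2 ± 2.06 to 99.8 ± 3.06 CPM. The same 10 melanosome genes with at most 3 control reads summed to 1062 CPM or more in the libraries of these rises as well.

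The interferon response list was called upward, with most of its members higher. Of 37 members tested, 27 rose and 1 fell, 28 and 2 adjusted over the list alone, with a median log2 fold change of 0.55 and adjusted p = 2.51e-06 (adjusted p = 0.335 with an estimated correlation). Ifi27 rose from 34.7 ± 1.36 to 56.7 ± 2.05 CPM, H2-K1, an MHC class I gene, from 39.5 ± 0.698 to 55.8 ± 0.927 CPM, and Bst2 from 136 ± 1.39 to 165 ± 1.48 CPM. Rtp4 rose from 1.46 ± 0.0212 to 3.43 ± 0.748 CPM. B2m, the light chain gene of MHC class I, named after its value was seen, was the member that fell, from 339 ± 5.45 to 300.2 ± 3.28 CPM. LPL overexpression replicate 4 stood apart in Irf1, an interferon-induced transcription factor gene placed in the activation list, with 286 CPM against 20.6 ± 1.36 CPM (SD, n = 3) in the other LPL overexpression libraries, a gene chosen after its values were seen. The 4 libraries with higher interferon genes also carried the pigment cell genes. The 10 melanosome genes with at most 3 control reads summed to between 1062 and 1111 CPM there.

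**Figure D3:**
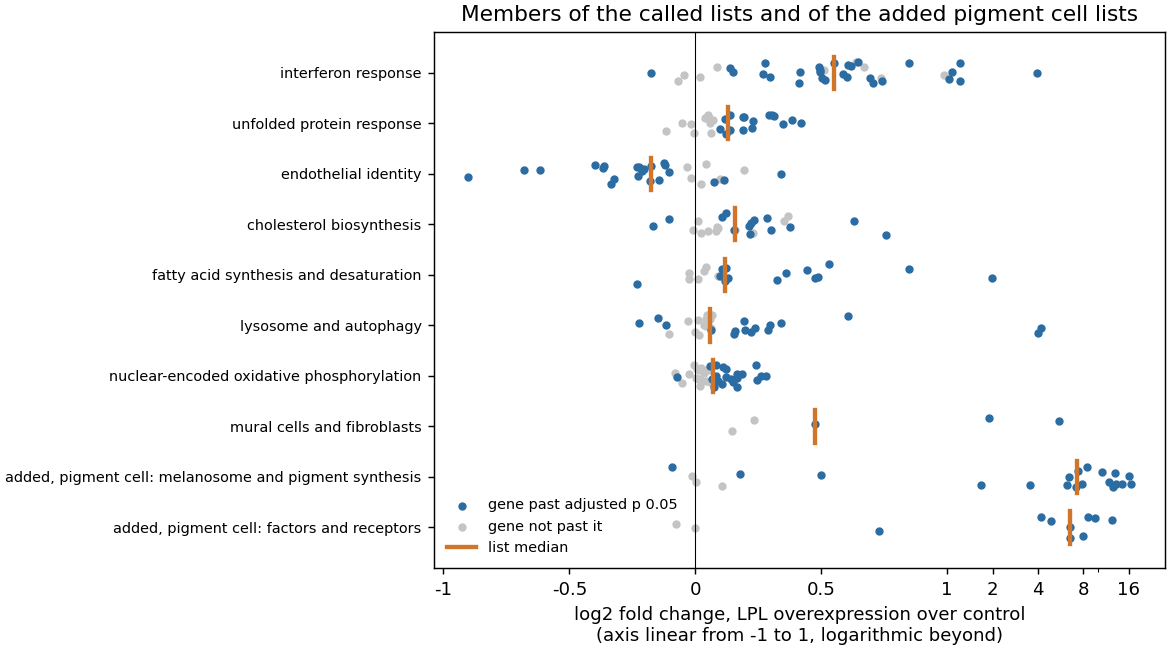
Log2 fold change of each tested member of the 8 called lists and the 2 added pigment cell lists, on an axis that is linear between -1 and 1 and logarithmic beyond; blue points passed an adjusted p of 0.05, grey points did not, and orange bars are list medians. The interferon median lies at 0.55, the endothelial identity median at -0.18 and the pigment medians at 7.27 and 6.50.

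Markers of other cell types of the pancreas, blood and fat were mostly too low to test. Of islet endocrine markers 0 were tested, of exocrine and epithelial markers 4 (1 rose, 2 fell), of macrophage and blood markers 3 (1 rose, 1 fell) and of adipocyte markers 2 (0 rose, 0 fell). Cd68 rose from 74.7 ± 3.03 to 98.7 ± 4.27 CPM and Cpb1 fell from 13.2 ± 0.437 to 8.98 ± 0.276 CPM. In the same lists, exocrine Cela1 had 2 control reads and a ratio of 26.0 (95% counting interval 6.92 to 219). Fcer1g, of the macrophage and blood list, fell from 0.557 ± 0.129 to 0.306 ± 0.0697 CPM, a call that ended with DESeq2 (adjusted p = 0.136) among other settings. Of 5 tested markers of mural cells and fibroblasts, 3 rose and 0 fell, with a median of 0.48 and adjusted p = 0.0384 (adjusted p = 0.306 with an estimated correlation). Cspg4, a proteoglycan gene also expressed by pigment cells, had 1 control read and a ratio of 63.2 (95% counting interval 11.1 to 2527), and Col3a1 was at 0.185 ± 0.0605 and 0.707 ± 0.0317 CPM. Notch3, whose log2 fold change is the list's median, rose from 2.97 ± 0.220 to 4.14 ± 1.08 CPM. Its call ended without LPL overexpression replicate 4 (adjusted p = 0.0668 in edgeR) among other settings. The call of the list ended without LPL overexpression replicate 2 (adjusted p = 0.0563) or LPL overexpression replicate 4 (adjusted p = 0.0590). The list's call also ended with upper-quartile factors, voom, TPM values and protein-coding genes only. The list's adjusted p over the settings of camera was between 0.00885 and 0.306. Its median was 1.00 without control replicate 2, 0.89 without control replicate 3 and 0.29 without LPL overexpression replicate 4, and it was above 1.00 without control replicate 1 or with no filter on low counts. In the libraries of this rise, the 10 melanosome genes with at most 3 control reads summed to 1062 CPM or more. Of 6 lymphatic endothelial markers, 2 rose and 2 fell (adjusted p = 0.888), and Lyve1 fell from 54.5 ± 0.848 to 44.9 ± 2.37 CPM. The 2 that rose had few control reads. Itga9 had 2 and a ratio of 93.4 (95% counting interval 25.6 to 775), and Prox1 had 3 and a ratio of 17.6 (5.77 to 87.2).

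Other lists held rises and falls and were not called by camera. Rises and falls numbered 8 and 4 of 27 in the ATF4 and amino acid response (adjusted p = 0.695), 10 and 7 of 42 in the cell cycle (0.778), and 13 and 9 of 30 in mesenchymal and matrix genes (0.340). They numbered 8 and 3 of 29 in heparan sulfate proteoglycans and their synthesis (adjusted p = 0.340), 9 and 12 of 33 in glycolysis and hypoxia (0.711), and 11 and 9 of 28 in the NRF2 response (0.497). They numbered 2 and 7 of 21 in p53 targets (adjusted p = 0.406), 2 and 1 of 7 in mitochondrially encoded genes (0.757), and 2 and 7 of 37 in ribosomal proteins (0.497). For histones they were 1 and 1 of 7 (adjusted p = 0.695) and for stress and dissociation genes 2 and 6 of 21 (0.497). Adjusted over the list alone, falls of matrix genes were 10 and of ribosomal proteins 4, and the other counts of this paragraph stayed as they were. Among the lists not called, the median, the mean and the direction of the test differed in sign for LPL processing, activation, angiogenesis, glycolysis, mitochondrially encoded, lymphatic, stress and p53 genes. Ccnd1, the cyclin D1 gene, fell from 2612 ± 45.4 to 2249 ± 60.2 CPM, Ndrg1 from 530 ± 11.7 to 359 ± 7.20 CPM and Nqo1 from 114 ± 4.09 to 81.0 ± 2.69 CPM. Bgn, the gene of the matrix proteoglycan biglycan, rose from 31.1 ± 2.27 to 73.4 ± 4.49 CPM. Gpc1, a glypican gene, had 0 control reads and 21.2 ± 2.21 CPM with overexpression, at least 571-fold more. As for the pigment cell genes in the same libraries, which cells gave its reads was not tested.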

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

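The tests of the pigment, endothelial and interferon patterns in this part were chosen after those results were seen.

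Among the 4 LPL overexpression libraries, 8 of 170 measures had 1 library far from the others by Dixon's ratio of gap to range, where chance gives about 1 in 20. Replicate 4 was highest for Mlph (38.5 CPM, nearest other 34.8, ratio 0.853), Selp (183 CPM, nearest 166, ratio 0.930) and Ptgs2 (51.3 CPM, nearest 49.6, ratio 0.842), and lowest for Ccnd1 (2158 CPM, nearest 2276, ratio 0.951). Replicate 2 was highest for Plag1 (ratio 0.834) and Lyve1 (ratio 0.936) and lowest for Rab27a (ratio 0.896). Replicate 3 was lowest for Uvrag (ratio 0.932). In the forward orientation, which the comparisons do not use, Lpl had 0 reads in the controls and 100 reads in all over the LPL overexpression libraries, 0.211% of the Lpl reads there. At the same rate the few Lpl reads of the controls would give 0.0169 forward reads, so their 0 shows no difference between the groups.

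Pigment cell genes were at or near 0 in the controls and present at like levels in all 4 LPL overexpression libraries. The tables argue against libraries made wholly from another cell type, because the endothelial identity list had a median log2 fold change of -0.18 with Pecam1 at 2145 CPM. Pigment-producing cells of another origin among these cells stay open, with Tyrp1 at 462, Pmel at 337 and Dct at 302 CPM, since 56.2% of the 16 listed lineage factors and receptors rose while Ednrb, Foxd3, Lef1, Ngfr and Tfap2b had 0 to 2 reads over each group, a share that does not decide. Of the melanosome list, 12 of 22 tested genes had more than 3 control reads, as had 6 of 11 of the lineage list, and 3 lineage genes stand in a fixed list. Pigment genes switched on within the MS-1 cells cannot be told apart from such cells, because the highest summed level was only 1.05 times the lowest over the 4 libraries, which both would give, and whether the Lpl reads come from cells with the pigment genes was not tested.

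Most endothelial identity genes were lower. Dilution by one share of other cells that express none of them would lower all of them by the same factor. However, 50% of the 28 members lay more than 3 standard errors, which measure only the spread between these libraries, from the list's median. Thbd stood at -0.90 while Tie1, chosen after its value was seen, was at -0.02 (SE 0.03), so such dilution does not account for the whole change. A smaller share of it remains open. Other cells that express some of the members would give unequal falls, so dilution by cells of that kind remains open too. The choice of scaling factors is argued against as well, since RLE or upper-quartile factors moved the list's median by at most 0.0225 on the log2 scale. On log2(TPM + 1) the median was -0.15, against -0.18 in the main fit. A bias common to these scalings was not tested. An effect of LPL itself remains open and untested, because the controls are wild type and the LPL and pigment genes come together.

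Most interferon response genes were higher. Without LPL overexpression replicate 4, where Irf1 stands apart, the median log2 fold change was 0.50 and camera at the preset correlation gave adjusted p = 7.66e-07, which argues against that library alone, while with an estimated correlation and all libraries the list was not called (adjusted p = 0.335). Interferon genes carried by the cells with the pigment genes cannot be told apart from a response of the MS-1 cells, because only 3.70% of the 27 higher members had at most 3 control reads and cells of both kinds can express the others. A response to the means of introducing LPL was not tested, since no vector-only library was analysed.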

How the results depend on the processing

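The alternatives were planned before the data were examined, except counts of both orientations and leaving out genes with at most 3 control counts. Apart from glmTreat, changed genes numbered between 4599 and 5939 over these alternatives and between 5155 and 5716 with 1 library left out. Genes changed at least 2-fold numbered 641 to 742 with 1 library left out. They numbered 429 (406 higher, 23 lower) on log2(TPM + 0.5) and 297 (283 higher, 14 lower) on log2(TPM + 1). These TPM settings changed the unit, the scaling and the model besides adding a pseudocount, so only the step from 429 to 297 isolates the pseudocount. Without genes of at most 3 control counts, which removes genes from the test, the 2-fold changes numbered 452 (382 higher). The 2-fold changes numbered 1006 (893 higher, 113 lower) with no filter and 464 (421 higher, 43 lower) with 1 CPM in 3 libraries, where more or fewer low genes were tested. Camera called 7 to 9 lists where it was run with the preset correlation, 0 with an estimated correlation, and fry called 22 by direction and 28 as mixed, which do not compare a list with other genes. DESeq2 gives no list test. The log2 fold change of Lpl was 7.09 on log2(TPM + 1), 8.05 on log2(TPM + 0.5), 11.65 to 13.39 with 1 library left out, and 12.04 to 12.24 otherwise. Same-numbered replicates did not deviate together (correlations -0.02, -0.04 and 0.02), and the replicate block over replicates 1 to 3 called 5737 genes and 8 lists. Among called genes besides Lpl, 154 were picked by the naming rule or held by the added lists. Of these, 148 kept their call in every alternative fit compared gene by gene that tested them, and none changed sign. The stricter threshold and glmTreat were not compared gene by gene. Against a fold of 1.5, glmTreat called 721 genes in all (617 higher, 104 lower), so many smaller changes did not pass there. Depth limits genes near the floor, such as Cd36.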

Other observations

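The counts over other splits were planned before their result was seen, while the genes of this part and the comparison of single libraries with their group were chosen after. Among genes outside the fixed lists, Met, the receptor of hepatocyte growth factor, rose from 94.7 ± 1.93 to 191 ± 3.01 CPM and Ccnd2, the cyclin D2 gene, from 88.0 ± 3.70 to 176 ± 5.60 CPM. Itga6, the laminin receptor subunit gene, fell from 360 ± 13.1 to 189 ± 3.29 CPM. Ackr3, a scavenging receptor of CXCL12, fell from 44.0 ± 2.49 to 21.4 ± 0.836 CPM, and Calcrl, the receptor of adrenomedullin, from 24.4 ± 1.70 to 12.1 ± 0.364 CPM. Within the angiogenesis list, Id2 and Id3, targets of BMP signalling, rose from 19.1 ± 0.538 to 61.3 ± 6.22 CPM and from 17.4 ± 0.766 to 45.1 ± 3.89 CPM, while Dll4, the Notch ligand of tip cells, had a log2 fold change of -0.83 (SE 0.08) and Angpt2 fell from 145 ± 5.82 to 87.3 ± 6.02 CPM. All 9 stood past the threshold of edgeR over all genes. Whether these changes arose in the MS-1 cells or came with the pigment cell genes of the same libraries was not tested.

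LPL overexpression replicate 4 differed at least 2-fold from the mean of the other LPL overexpression libraries in 7 of 10025 genes with a mean of at least 5 CPM, against 0 to 2 genes for every other library within its group. Irf1, an interferon-induced transcription factor, was at 286 CPM there, and Socs3 at 39.8 CPM against 11.5 ± 0.964 CPM (SD, n = 3) in the other LPL overexpression libraries. Irgm2, Zfp36, Clec2d and Irf9 were also higher, while the pseudogene Gm12696 was at 0.468 CPM against 9.37 ± 0.429 CPM. None of the 7 differed between the groups past the threshold in edgeR.

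The real split was the 1 of 35 with as many changed genes, 5888, and the highest of the others called 2. For genes changed at least 2-fold it was again the 1 of 35 with as many, 688, and the highest of the others called 0. Every other split has a side that mixes both groups. The difference between groups then widens the spread within that side, so few calls were bound to appear there. These counts cannot exclude a chance difference between cultures, since the replicates may not be separate cultures. For the lists, 2 of the 35 splits, the real one included, called 8 or more, with 8 in the highest other. That other split set LPL overexpression replicates 2, 3 and 4 against the controls and replicate 1. It keeps most of the contrast between the groups, so its count does not show what chance gives. Chance is thus not excluded for the number of lists called, and these splits cannot decide it.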
